A study of Mus musculus with 6 samples.

How the data were processed

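Total RNA of cultured mouse mammary tumor explant cells was sequenced on an Illumina HiSeq 2000, per the labels, in 3 libraries of control cells (shCON) and 3 of CdGAP-depleted cells (shCdGAP). Groups and replicate numbers were taken from the labels; the cell type label reads the same for all 6 samples, and the genotype label tells the groups apart. Per the submitters' processing notes, which give no roles or order, the tools were Trimmomatic, TopHat2 2.0.13, featureCounts and DESeq2, with the mouse build mm10. The annotation release and the handling of strand are not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart.

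The authors deposited 1 table of 41214 genes with an FPKM value per library. Per the file headers it also holds the authors' own DESeq2 comparison of shCdGAP over control: a mean signal per gene (the mean of reads divided by size factors), a log2 fold change with its standard error, a test score, and a p-value with its adjusted value. The deposited FPKM values had already been divided by size factors. The size factors themselves were not given. For each library 1 factor was fitted to bring values to whole reads, starting from the commonest value among genes seen in that library only, taken as 1 read. Multiplying each FPKM by the gene's deposited mean signal over its mean FPKM, and by the library's fitted size factor, gave whole reads for 100% of values (tolerance 1e-06). These recovered reads served for depth, for the filter on low genes, for CPM and for limma-voom. Total reads ranged from 19176540 to 26824249 per library, and 22322 genes had reads. Gene positions were taken from the GENCODE M21 annotation of the same build, in which 40254 of the identifiers were found.

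The design fixed before the data were examined assumed raw counts and a count model, with limma on log2(value + 1) if the table held none. The table holds FPKM, so limma was the main test. Genes entered with at least 10 reads, scaled to the median depth, in at least 3 libraries and at least 15 reads in all, which left 13483. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The fit had the group as its single term, with limma's empirical Bayes step (trend and robust), 2-sided tests and Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. Values are means ± SD over 3 libraries. In R 4.3.3 with limma 3.58.1, gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 on log2(FPKM + 1), adjusted over the 29 lists with at least 5 tested members, of which 1 is not reported here. Camera with an estimated correlation, camera on ranks, and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were alternatives. Of 11 lists called at the preset correlation, 0 were called with an estimated one, and 3 were at an unadjusted p under 0.05 there. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

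The genes named are 14 fixed ones (Arhgap31, Cdh1, Zeb2, Zeb1, Snai1, Snai2, Twist1, Vim, Cdh2, Fn1, Erbb2, Rac1, Cdc42 and Ctbp1), the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and a non-provisional symbol, and up to 4 members of each list with the smallest p among changed members, or the highest CPM where none changed. Names outside this rule are marked where they stand.

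The groups share replicate numbers. The deviations of same-numbered libraries from their group means correlated across genes at 0.43, 0.39 and 0.34 for numbers 1, 2 and 3, so the numbers were taken to pair the libraries. This pairing comes from the data and not from the labels, and number 2 of shCdGAP correlated at 0.35 with number 3 of shCON, so numbers 2 and 3 were not separated. The deviations within a group are tied to each other through its mean. The 3 correlations are therefore not independent, and they bear mainly on a likeness of the libraries numbered 1. A fit with the replicate number as a block was an alternative.

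The steps were tested on simulated data before use. Reads were drawn for the real genes at the real depths, with 1 dispersion of 0.0206 for every gene, and turned into FPKM. In these reads 200 genes were changed 2-fold or 4-fold, and a further list was raised 1.5-fold. The filter was passed by 13430 genes. For this comparison of 3 against 3 libraries the limma step called 92.0% of genes raised 2-fold, 100% of those raised 4-fold, 87.8% of those lowered 2-fold and 100% of those lowered 4-fold, and 3.96% of its calls were unchanged genes. The simulated spread did not include a library that stands apart or a dispersion that differs between genes. Far fewer genes changed than the 2838 called in the real data, so these rates may not hold there. Alternatives tried were library size scaling, other filters, a pseudocount of 0.1 FPKM, limma-voom on recovered reads, the block, removal of trends on gene length or GC content, trimmed mean and quantile scaling, each library left out, both libraries numbered 1 left out, and the authors' table. No count test was run on the recovered reads. Weights per library (limma's arrayWeights) were also tried because of the library that stands apart, and were dropped because they did not converge.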

Results

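Total RNA was sequenced from mouse mammary tumor explant cells kept in culture. The cells derived from NMuMG, a mouse mammary epithelial line, and expressed Neu-NT, an activated form of the receptor tyrosine kinase ErbB2. A control population carrying a control hairpin (shCON, 3 libraries) was set against a population depleted of CdGAP by a short hairpin RNA (shCdGAP, 3 libraries). CdGAP, the product of Arhgap31, is a GTPase-activating protein for Cdc42 and Rac1, and the study asked about its part, with the transcription factor Zeb2, in the repression of the E-cadherin gene Cdh1. The libraries held 23151324, 22088774 and 25893195 gene-assigned reads for shCdGAP replicates 1, 2 and 3, and 19176540, 26824249 and 25978281 for shCON. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Within each group, every pair of libraries differed by more than counting error on reads, the 1 source of noise that this comparison covers. Replicate 1 of shCdGAP stood apart from its group: its correlation across genes, on the log2 scale, was 0.952 and 0.942 with replicates 2 and 3, which correlated at 0.996 with each other. Genes are not independent replicates in these correlations.

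Arhgap31, the target of the hairpin (ENSMUSG00000022799, chromosome 16, 38598340 to 38713274 of mm10, minus strand), was lower in every shCdGAP library than in every shCON library. It stood at 0.149, 0.826 and 0.748 FPKM in shCdGAP replicates 1, 2 and 3, from 38, 202 and 207 reads, and at 1.19, 1.30 and 1.35 FPKM in shCON, from 256, 397 and 402 reads. The group means were 0.574 ± 0.370 and 1.28 ± 0.0810 FPKM (SD, n = 3), a ratio of 0.449. The fitted log2 fold change was -0.56 (SE 0.19) and missed the threshold in the limma test (adjusted p = 0.0836). In the authors' deposited comparison it was -0.99 (SE 0.48) and missed the threshold as well (adjusted p = 0.125, DESeq2). Without shCdGAP replicate 1, the library with the lowest level, the fold change was -0.35 and passed it (adjusted p = 0.0171, limma). The direction matched the labels in all 6 libraries. The median expressed gene of chromosome 16 was itself 0.29 lower on the log2 scale in shCdGAP, relative to all expressed genes, and those of chromosomes 8 and 2, which hold Cdh1 and Zeb2, were 0.23 higher and 0.21 lower. These medians cover genes with a mean of at least 3 FPKM. The added 1 FPKM shrinks their changes less than that of Arhgap31, so the values are not on an equal footing.

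Cdh1, encoding E-cadherin (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246, plus strand), rose from 50.7 ± 11.1 to 168 ± 16.1 FPKM (SD, n = 3). The log2 fold change was 1.73 (SE 0.19, adjusted p = 0.0022, limma). Zeb2 (ENSMUSG00000026872, chromosome 2, 44983632 to 45117395, minus strand) fell from 1.75 ± 0.416 to 0.893 ± 0.0742 FPKM, with a log2 fold change of -0.53 (SE 0.13, adjusted p = 0.0330, limma). The call on Zeb2 was lost without shCdGAP replicate 2 (adjusted p = 0.118), shCdGAP replicate 3 (0.0817), shCON replicate 2 (0.0693) or shCON replicate 3 (0.085), and with no filter on low genes (0.0589). Its log2 fold change in these fits was -0.60 to -0.50. The authors' deposited comparison called Zeb2 lower, with a log2 fold change of -0.94 (SE 0.22, adjusted p = 2.21e-04, DESeq2). Snai1, another repressor of Cdh1, fell from 10.6 ± 0.368 to 5.06 ± 0.393 FPKM (log2 fold change -0.93, adjusted p = 0.00179, limma). Snai2 stood at 1.01 ± 0.722 FPKM in shCdGAP and 2.50 ± 0.773 in shCON and missed the threshold (log2 fold change -0.84, adjusted p = 0.0887), but passed it with the replicate number as a block (adjusted p = 0.0218) without shCdGAP replicate 1 (0.00505) and without both libraries numbered 1 (7.40e-04). Zeb1 was at 3.06 ± 0.149 and 3.16 ± 0.231 FPKM and did not differ beyond the replicate spread (adjusted p = 0.85). Twist1 had 0 reads in all 6 libraries, with a floor of 3 reads per library. The GTPases Rac1 (log2 fold change 0.12, adjusted p = 0.529) and Cdc42 (0.030, adjusted p = 0.848) did not pass the limma test. The co-repressor gene Ctbp1 did not pass it either (0.29, adjusted p = 0.12), except without shCdGAP replicate 1 (adjusted p = 0.0129) and without both libraries numbered 1 (0.00925).

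**Figure D1:**
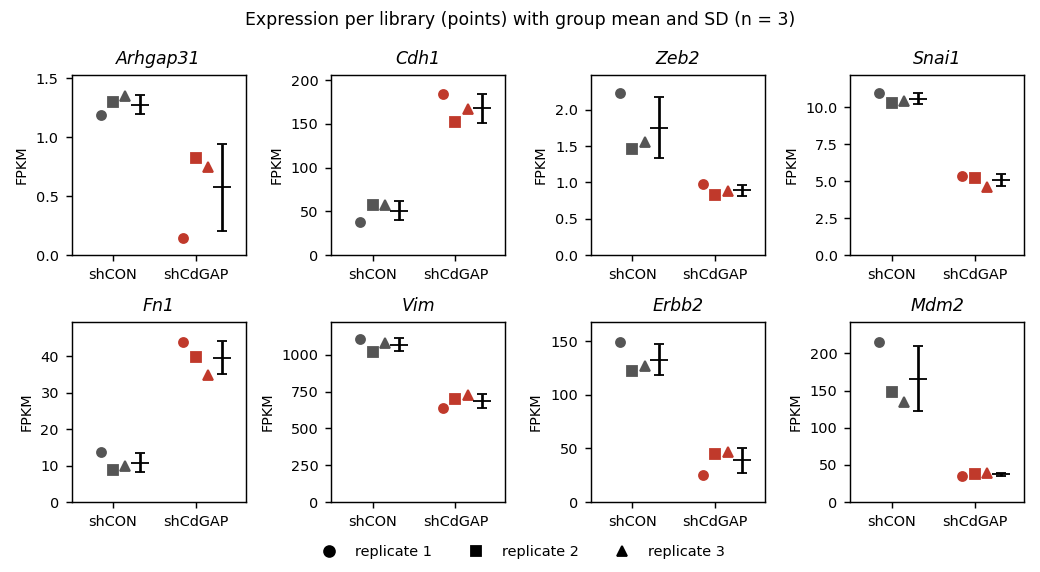
FPKM (vertical axes, linear, from 0) of 8 genes in each library, with circles, squares and triangles for replicates 1, 2 and 3 of shCON (grey) and shCdGAP (red), and bars for the group mean and SD (n = 3). Cdh1 and Fn1 lie higher in all 3 shCdGAP libraries than in any shCON library, the other 6 genes lie lower, and Arhgap31 is lowest in shCdGAP replicate 1, at 0.149 FPKM.

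Across the transcriptome, 2838 of 13483 tested genes changed, 1337 higher and 1501 lower in shCdGAP (limma on log2(FPKM + 1), adjusted p under 0.05). Which direction held more genes depended on the scaling, since library size alone gave 1112 higher and 1705 lower, whereas trimmed mean and quantile scaling, both added after the data were seen, gave 1557 and 1361, and 1463 and 1421. It depended on the filter as well, with 1038 higher and 922 lower among genes of at least 5 CPM. Of the 2838 genes, 827 had an absolute log2 fold change of at least 1, with 362 higher and 465 lower. The ranges of the groups did not overlap for 5945 tested genes (44.1%), against 10% by chance. The authors' deposited table called 4033 of 16970 genes, and 2791 genes were called in both, all 2791 in the same direction. The count of changed genes moved with single libraries: it was 5435 without shCdGAP replicate 1, and 1469, 1738, 1251 and 1344 without shCdGAP replicate 2 and shCON replicates 1, 2 and 3. Calls within the gene lists reported moved likewise, with 207 members changed, counted once per list, 355 without shCdGAP replicate 1, 128 and 165 without shCdGAP replicates 2 and 3, and 140, 115 and 120 without shCON replicates 1, 2 and 3. With an estimated correlation, camera called 0 of these lists in any of 20 fits, these and the other settings included (lowest adjusted p = 0.268). Of the changed genes, 2835 were also called in the same direction without shCdGAP replicate 1.

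Lbp, the lipopolysaccharide-binding protein, had the largest rise by the rule for named genes, from 0.728 ± 0.213 to 91.9 ± 7.89 FPKM (SD, n = 3), a log2 fold change of 5.75 (SE 0.13, adjusted p = 2.12e-05, limma). Complement C3 rose from 0.671 ± 0.468 to 50 ± 18.2 FPKM, the hyaluronan-binding protease Habp2 from 0.715 ± 0.230 to 52.6 ± 13.4, and Gc, the vitamin D-binding protein, from 9.87 ± 5.84 to 227 ± 53.9. Foxj1, a transcription factor of motile cilia, rose from 1.17 ± 0.592 to 52.7 ± 16.5 FPKM, and the epithelial ETS factor Ehf from 0.0545 ± 0.0364 to 12.6 ± 3.98. Cdh16, a cadherin of kidney epithelium, the sulfotransferase Sult1c2, the alkaline phosphatase Alpl and the complement protease C1s1 completed the 10 largest rises, with log2 fold changes of 4.30, 3.78, 3.67 and 3.66. This order is on the log2(FPKM + 1) scale, which shrinks changes of low genes. By the ratio of mean FPKM, Alpl rose 308-fold, from 0.0451 to 13.9 FPKM, and Ehf 231-fold, against 126-fold for Lbp. C1s1 has a close paralog, so its reads are uncertain, and its log2 fold change was 2.99 without shCdGAP replicate 1, where it stood at 58.7 FPKM against 16.1 and 11.6 in replicates 2 and 3. That of Gc was 4.56, and 3.98 without shCON replicate 1.

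Among the largest falls, Capg, an actin-capping protein, went from 122 ± 12.9 to 1.64 ± 0.302 FPKM (SD, n = 3), a log2 fold change of -5.54 (SE 0.13, adjusted p = 2.12e-05, limma). Gatm, an enzyme of creatine synthesis, fell from 44.2 ± 3.34 to 0.0494 ± 0.0391 FPKM. Arap3, a GTPase-activating protein for Arf proteins, fell from 33.9 ± 4.04 to 0.5 ± 0.259 FPKM. The surface proteins Cd34 and Procr fell from 17.4 ± 4.55 to 0.224 ± 0.0388 and from 13.8 ± 0.0533 to 0.0350 ± 0.0111 FPKM. The log2 fold changes of Praf2, Prl2c3, S100a7a, Ptprn and Dynap, which complete the 10 largest falls, were -4.96, -4.46, -4.39, -4.37 and -4.07. By the ratio of mean FPKM, Gatm and Procr fell 894-fold and 394-fold, against 74.0-fold for Capg. Prl2c3 belongs to a family of near-identical genes that share reads, and its call was lost without each of the 3 shCON libraries (adjusted p = 0.0593, 0.0594 and 0.0536 for replicates 1, 2 and 3) or without shCdGAP replicate 2 (0.0502). Its log2 fold change was -3.55 without shCdGAP replicate 1 and -5.26 without replicate 3.

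Of 24 tested genes of epithelial junctions and polarity, 10 were higher and 2 lower, and 12 did not pass (11 and 2 when adjusted over the list alone), and the list was called by camera (adjusted p = 6.32e-04; adjusted p = 0.363 with an estimated correlation). Besides Cdh1, the desmosomal cadherin Dsg2 rose from 0.0875 ± 0.0122 to 3.84 ± 0.188 FPKM (SD, n = 3), the tight junction gene Ocln from 2.87 ± 0.184 to 10.8 ± 2.45, and Cgn, encoding cingulin, from 5.90 ± 0.380 to 16.5 ± 2.14. The members that fell were Cldn6 and Epcam, named here after their values were seen, and Epcam had 0 FPKM in every shCdGAP library against a mean of 0.632 in shCON. Of 15 epithelial keratins and epithelial regulators, 6 rose and 2 fell (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0161, and adjusted p = 0.363 with an estimated correlation). Muc1 and Cd24a rose, with log2 fold changes of 2.51 and 1.05, whereas the luminal transcription factor Foxa1 fell (-1.77).

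Mesenchymal genes went both ways, with 7 of 20 tested members higher and 5 lower (8 and 6 when adjusted over the list alone; camera adjusted p = 0.388). Without any single shCON library, 4 were higher. Fn1, encoding fibronectin, rose from 10.8 ± 2.65 to 39.5 ± 4.53 FPKM (SD, n = 3), and Loxl2, a lysyl oxidase, from 0.226 ± 0.0207 to 9.83 ± 0.279. Col6a1 also rose (log2 fold change 2.16), as did the N-cadherin gene Cdh2 (0.64, adjusted p = 0.0253, limma), although Cdh2 lost its call without shCdGAP replicate 2 (adjusted p = 0.0888) and without shCON replicates 1, 2 or 3 (0.0853, 0.106 and 0.0887). The authors' deposited comparison called Cdh2 higher (log2 fold change 0.68, adjusted p = 0.0013, DESeq2). Vim, encoding vimentin, fell from 1068 ± 43.4 to 688 ± 47.3 FPKM, and the fibronectin receptor subunit gene Itga5 fell (log2 fold change -1.20). Among 18 transcription factors and co-repressors of the epithelial-mesenchymal transition, Twist2, Sox4 and Id2 rose and Snai1, Zeb2 and Hmga2 fell (3 and 3 also when adjusted over the list alone; camera adjusted p = 0.905), Sox4 being named after its value was seen. The call on Twist2 was lost without shCON replicate 1, 2 or 3 (adjusted p = 0.0540, 0.0582 and 0.0558, limma). The authors' deposited comparison called Twist2 higher (log2 fold change 3.66, adjusted p = 1.71e-13, DESeq2). Without shCdGAP replicate 1 the list had 6 higher and 6 lower, and without shCON replicate 2 or 3, 1 and 2. The list's median was -0.033 and its mean 0.015, so they differed in sign.

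Of 26 tested ErbB receptors, ligands and feedback genes, 13 were lower and 2 higher (15 and 2 when adjusted over the list alone; camera adjusted p = 6.99e-04, and adjusted p = 0.363 with an estimated correlation). Without shCdGAP replicate 2 or shCON replicate 1, 8 were lower and 1 higher, and without shCON replicate 2 or 3, 9 and 1. Erbb2 itself fell from 133 ± 14.7 to 38.8 ± 11.5 FPKM (SD, n = 3), a log2 fold change of -1.79 (SE 0.24, adjusted p = 0.00486, limma). Reads of the introduced Neu-NT sequence and of the endogenous gene cannot be told apart in these values. The ligand gene Btc fell from 9.26 ± 1.72 to 1.33 ± 0.397 FPKM, and the feedback inhibitors Errfi1 and Spry4 fell by 1.93 and 1.55 on the log2 scale. Immediate-early genes, which respond within minutes to growth signals, had 6 lower and 1 higher of 21 (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0402, and adjusted p = 0.651 with an estimated correlation). Egr1 fell from 11.1 ± 4.68 to 1.55 ± 0.559 FPKM. That list's call was lost with the replicate number as a block (adjusted p = 0.053), with library size scaling alone (0.059), among genes of at least 5 CPM (0.119), without shCdGAP replicate 3 (0.0673), without shCON replicate 1 (0.154) and without both libraries numbered 1 (0.133). The list had 10 lower and 2 higher without shCdGAP replicate 1, 6 and 3 with the block, and 3 or 4 lower without any other single library.

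Cyclin-dependent kinase inhibitors and p53 targets had 9 lower and 0 higher of 28 tested members (9 and 0 when adjusted over the list alone; camera adjusted p = 0.00246, and adjusted p = 0.363 with an estimated correlation). Mdm2, the ubiquitin ligase that targets p53 and is itself a p53 target, fell from 166 ± 43.5 to 37.7 ± 2.19 FPKM (SD, n = 3). Zmat3, Sesn2 and Eda2r fell by 1.44, 1.30 and 0.99 on the log2 scale. Of this list, 14 members were lower and 2 higher without shCdGAP replicate 1, 10 and 2 with the block, and 6 lower without shCdGAP replicate 2 or shCON replicate 2. DNA replication and mitosis genes had no member past the limma threshold, with 0 of 40 and 0 of 39, and no member passed when adjusted over the list alone. At an unadjusted p under 0.05, limma had 3 DNA replication genes, all lower, and 0 mitosis genes, limma-voom called 0 of either list, and the authors' deposited table called 2 and 0. Their list medians were -0.53 in both cases (camera adjusted p = 0.0535 and 0.256, and adjusted p = 0.800 and 0.900 with an estimated correlation). Replicate 1 of shCdGAP held these genes far below its group: its median was 3.39 log2 units below the mean of replicates 2 and 3 for mitosis genes, and 2.14 below for DNA replication genes. That library also held the least Arhgap31, at 0.149 FPKM. Without it, 21 mitosis genes were higher and 0 lower, with a list median of 0.56 (camera adjusted p = 5.03e-06, and adjusted p = 0.631 with an estimated correlation). The DNA replication list then had 5 higher and 3 lower, with a median of 0.21 (adjusted p = 0.229). With the replicate number as a block, the DNA replication list passed the test as lower (adjusted p = 0.00711, and adjusted p = 0.786 with an estimated correlation), as it did without shCdGAP replicate 2 or 3 or shCON replicate 1 (adjusted p = 0.00236, 0.00116 and 0.0339) and with 5 other settings of filter, scaling or test (0.0177 to 0.0467). With an estimated correlation, adjusted p for DNA replication was at least 0.733 in each of these fits except the test on ranks, which has no such form. The mitosis list passed as lower without shCdGAP replicate 2 or 3 (adjusted p = 0.00947 and 0.0182, and adjusted p = 0.744 and 0.765 with an estimated correlation). With fry, which tests for a shared direction, adjusted p was 0.504 for DNA replication and 0.658 for mitosis.

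Of 23 tested targets of NF-kappaB, cytokines and chemokines, 13 were higher and 2 lower (13 and 4 when adjusted over the list alone; camera adjusted p = 3.25e-04, and adjusted p = 0.622 with an estimated correlation). Besides C3, the adhesion receptor Vcam1 rose from 1.20 ± 0.151 to 13.9 ± 2.11 FPKM (SD, n = 3), and the monocyte-attracting chemokines Ccl7 and Ccl2 from 4.29 ± 0.571 to 23.2 ± 3.39 and from 64.5 ± 3.17 to 221 ± 64.5. The members that fell were Lif and Csf2, cytokines named here after their values were seen. In shCdGAP replicate 1 this list's median lay 0.60 log2 units below the mean of replicates 2 and 3, and without that library 18 members were higher and 5 lower, while 7 or 8 were higher without shCdGAP replicate 2, shCON replicate 2 or shCON replicate 3, and 0 or 1 lower without any single library other than shCdGAP replicate 1. Of 33 tested interferon-stimulated genes, 14 were lower and 1 higher, and 18 did not pass (15 and 1 when adjusted over the list alone; camera adjusted p = 9.84e-04, and adjusted p = 0.631 with an estimated correlation). Oasl1 fell from 16.7 ± 0.381 to 2.37 ± 0.318 FPKM, and Mx1 and Oas3, antiviral effectors, from 1.55 ± 0.0344 to 0.103 ± 0.0564 and from 2.36 ± 0.450 to 0.0133 ± 0.0119. Without shCdGAP replicates 2 or 3 or shCON replicate 3, 9 were lower, no member was higher without any single shCON library or with the block, and 20 were lower and 2 higher without shCdGAP replicate 1. When only genes with a mean of at least 5 CPM were tested, the interferon list lost its call (adjusted p = 0.332), with a median log2 fold change of -0.0018.

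TGF-beta ligands, receptors and targets had 7 higher and 1 lower of 29 (8 and 1 when adjusted over the list alone; camera adjusted p = 0.0194, and adjusted p = 0.549 with an estimated correlation), and the call was lost without shCdGAP replicate 1 (adjusted p = 0.0577), where 9 were higher and 4 lower. Without shCdGAP replicate 2 or shCON replicate 2 or 3, 4 were higher and 0 lower. Tgfb2 rose from 0.320 ± 0.0519 to 2.78 ± 0.448 FPKM (SD, n = 3), and Tgfbr1 from 16.1 ± 0.758 to 33.6 ± 0.477. Sterol and fatty acid synthesis genes had 7 higher and 0 lower of 32 (7 and 0 when adjusted over the list alone; camera adjusted p = 7.05e-04, and adjusted p = 0.716 with an estimated correlation). Hmgcs1, of cholesterol synthesis, rose from 60.7 ± 11.8 to 185 ± 74.4 FPKM, a call lost without shCdGAP replicate 2, shCON replicate 2 or shCON replicate 3 (adjusted p = 0.0547, 0.0733 and 0.0724, limma). In shCdGAP replicate 1 this list's median lay 0.79 log2 units above the mean of replicates 2 and 3. Without that library 14 members were higher and 4 lower, and the list's median log2 fold change went from 0.69 to 0.34 (camera adjusted p = 0.0169). The block gave 11 higher, whereas 1 member was higher without shCdGAP replicate 2 or shCON replicate 1 and 0 without shCON replicate 2 or 3 (limma). Of 11 mitochondrially encoded genes, 8 rose and 0 fell (10 and 0 when adjusted over the list alone; camera adjusted p = 1.83e-04, and adjusted p = 0.549 with an estimated correlation). Without shCON replicate 2 or 3, 5 were higher. All genes with a mitochondrial (mt-) symbol, not only these 11, took 3.24%, 2.51% and 2.32% of reads in shCdGAP replicates 1, 2 and 3. In shCON they took 1.68%, 1.69% and 1.58%. Of 40 ribosomal protein genes, Rpl13 and Rps18 rose and none fell (0 and 0 when adjusted over the list alone; camera adjusted p = 9.84e-04, and adjusted p = 0.731 with an estimated correlation). That list's call was lost under quantile normalization (adjusted p = 0.203), and these genes have many processed copies that share reads. The ribosomal list's medians, relative to the mean of the 6 libraries, overlapped between the groups, at 0.26, -0.056 and 0.12 in shCdGAP replicates 1, 2 and 3 and 0.079, -0.23 and -0.19 in shCON. Both libraries numbered 1 lay above the others of their group, by 0.24 in shCdGAP and 0.30 in shCON, and without shCdGAP replicate 1 the list's median log2 fold change went from 0.22 to 0.13 (camera adjusted p = 0.0479), with 4 members higher and 0 lower. Members higher numbered 3 with the block. The call on Rpl13 was lost without shCdGAP replicate 3 or shCON replicates 2 or 3 (adjusted p = 0.0880, 0.136 and 0.131), and that on Rps18 without any single library other than shCdGAP replicate 1 (0.0617 to 0.148). Both were also lost with no filter on low genes (0.0559 and 0.0647) and under quantile normalization (0.0584 and 0.0571).

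**Figure D2:**
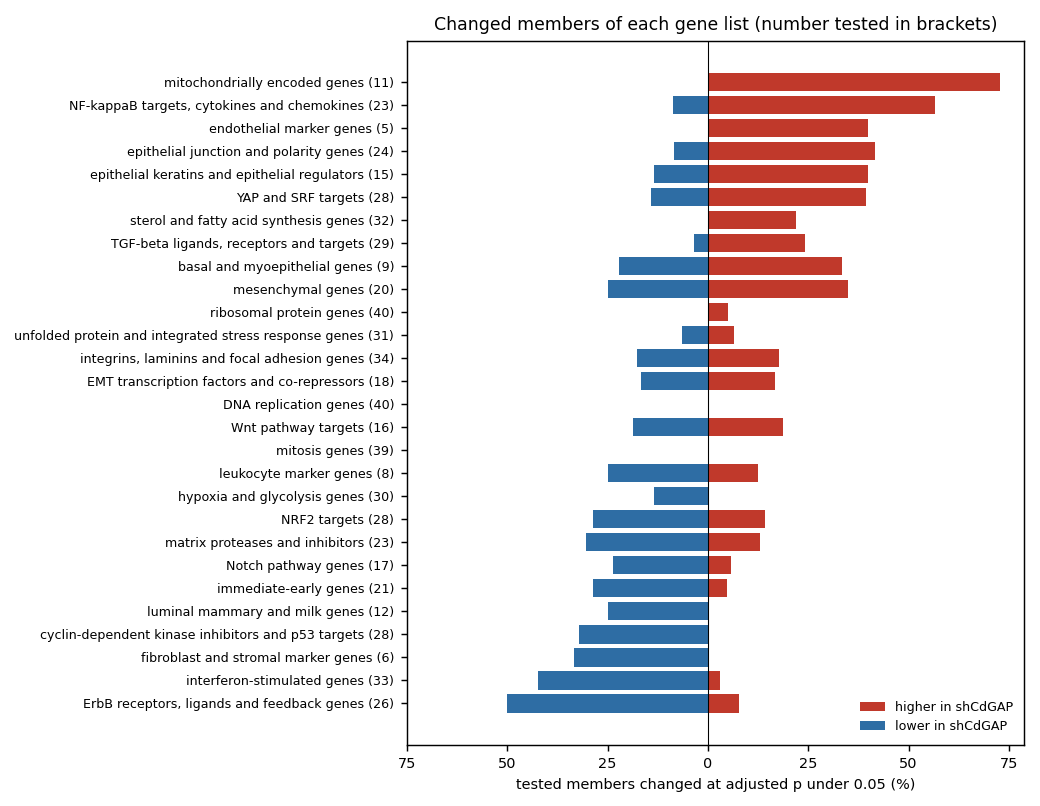
Percent of the tested members of each of 28 gene lists that changed at adjusted p under 0.05 (limma), with members higher in shCdGAP drawn to the right (red), members lower to the left (blue), and the number tested in brackets. ErbB receptors, ligands and feedback genes had 13 of 26 members lower, and mitochondrially encoded genes 8 of 11 higher.

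The lists that follow were not called by camera. Integrins, laminins and focal adhesion genes had 6 higher and 6 lower of 34 (adjusted p = 0.722), and Itga6 fell from 60.8 ± 11.6 to 12.5 ± 1.06 FPKM (SD, n = 3). Matrix proteases and inhibitors had 3 higher and 7 lower of 23 (adjusted p = 0.107), with Serpine2 lower (-1.98) and Adamts1 higher (2.04), and the list passed without both libraries numbered 1 (adjusted p = 0.0344, and adjusted p = 0.5 with an estimated correlation). Targets of YAP and SRF had 11 higher and 4 lower of 28 (adjusted p = 0.107), with Nuak2 (2.39) and Tpm1 (0.76) higher, and the list passed among genes of at least 5 CPM (adjusted p = 0.0484, and adjusted p = 0.715 with an estimated correlation). Without any single library other than shCdGAP replicate 1, 3 to 7 of these targets were higher. Wnt pathway targets had 3 higher and 3 lower of 16 (adjusted p = 0.722), and Wisp1 rose (2.16). Notch pathway genes had 1 higher and 4 lower of 17 (adjusted p = 0.491), with Notch4 (-1.47) and Dll4 (-1.29) lower. Hypoxia and glycolysis genes had 0 higher and 4 lower of 30 (adjusted p = 0.180), and the list passed without shCdGAP replicate 1 (adjusted p = 0.0169, and adjusted p = 0.631 with an estimated correlation), with 2 higher and 11 lower. The block gave 4 higher and 5 lower of that list, and 1 was lower without any single other library. Unfolded protein and stress response genes had 2 higher and 2 lower of 31 (adjusted p = 0.256), 2 and 6 with the block, 1 and 2 without shCdGAP replicate 2 or shCON replicate 1, 1 and 3 without shCdGAP replicate 3, and 0 and 2 without shCON replicate 2 or 3. Targets of NRF2 had 4 higher and 8 lower of 28 (adjusted p = 0.905), with Gclm higher (1.14) and Gsta1 lower (-2.46), and with a median of 0.061 against a downward test direction. When adjusted over the list alone, higher and lower members numbered 7 and 8 for integrins and focal adhesion, 13 and 6 for targets of YAP and SRF, 4 and 4 for Wnt, 3 and 4 for Notch and 7 and 8 for NRF2, and the other lists named with them had equal counts both ways of adjusting. Without shCdGAP replicate 1, higher and lower members numbered 10 and 11 for integrins and focal adhesion, 6 and 5 for Wnt, 4 and 6 for Notch, 5 and 5 for the unfolded protein and stress response and 8 and 12 for NRF2. For integrins and focal adhesion they numbered 3 and 4 without shCdGAP replicate 2, 3 and 6 without shCdGAP replicate 3, 2 and 5 without shCON replicate 1, and 2 and 4 without shCON replicate 2 or 3. For NRF2 they numbered 3 and 3 without shCdGAP replicate 2, 2 and 4 without shCON replicate 1, 2 and 3 without shCON replicate 2 or 3, and 4 and 5 with the block. No Notch gene was higher without shCdGAP replicate 3 or shCON replicate 2 or 3.

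Markers of cell types that a mammary explant could hold were few among the expressed genes. Luminal and milk genes had 0 higher and 3 lower of 12 (camera adjusted p = 0.107; 0.0467 in limma-voom, and adjusted p = 0.405 there with an estimated correlation), with the milk protein gene Csn3 falling from 5.87 ± 0.857 to 0.512 ± 0.110 FPKM (SD, n = 3). Basal and myoepithelial genes had 3 higher and 2 lower of 9 (adjusted p = 0.701). Fibroblast and stromal markers had 0 higher and 2 lower of 6 (adjusted p = 0.293), endothelial markers 2 higher and 0 lower of 5 (adjusted p = 0.812), and leukocyte markers 1 higher and 2 lower of 8 (adjusted p = 0.388). Without shCdGAP replicate 1, 4 fibroblast and stromal markers were lower, and 1 endothelial marker was lower besides the 2 higher. The endothelial markers that were higher, Egfl7 and Flt1, both lost their calls without shCdGAP replicate 2 (adjusted p = 0.0626 and 0.130) and without shCON replicate 1 (0.0663 and 0.124), 2 (0.102 and 0.122) or 3 (0.0993 and 0.117), and Flt1 lost its call with the block (0.0832). Basal genes had 3 higher and 1 lower without shCdGAP replicate 2 and 1 and 1 without shCON replicate 2. Leukocyte markers had 0 higher and 1 lower without shCdGAP replicate 2 or shCON replicate 2 or 3, 2 and 1 without shCdGAP replicate 3, and 1 and 1 without shCON replicate 1. Adjusted over the list alone, endothelial markers had 2 higher and 2 lower, and the other marker lists tested had the counts given. The endothelial median was -0.069 and the mean 0.13, with an upward test direction. Of 12 adipocyte markers, 4 were tested, too few for camera, and Fabp4 and Cidec fell, Cidec losing its call with the replicate block (adjusted p = 0.0563). Fabp4 lost its call without shCdGAP replicate 2 or shCON replicate 3 (adjusted p = 0.0518 and 0.0532), and Cidec without shCdGAP replicate 2 or shCON replicates 1, 2 or 3 (0.0552, 0.0592, 0.0717 and 0.0519).

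**Figure D3:**
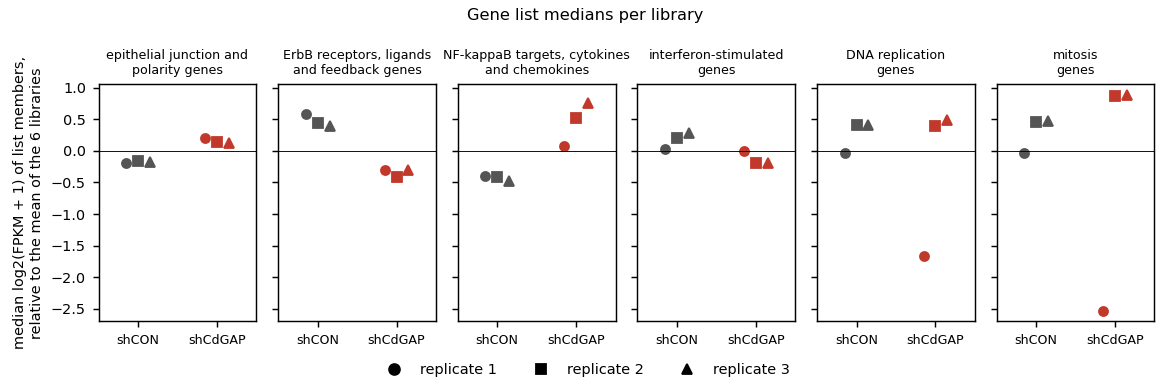
Median over list members of log2(FPKM + 1) relative to the mean of the 6 libraries (vertical axis, log2 units), for 6 gene lists in each library, with circles, squares and triangles for replicates 1, 2 and 3 of shCON (grey) and shCdGAP (red). The mitosis median was -2.53 in shCdGAP replicate 1, and 0.87 and 0.88 in replicates 2 and 3.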

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

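Chosen after the data were seen were trimmed mean (TMM) and quantile scaling, the authors' deposited table, leaving out both libraries numbered 1, removal of a GC trend, camera with an estimated correlation in each alternative, and the block with a length or GC trend removed; the others were planned. Not run were size factors in place of TMM, since the deposited values already carry them, and a count model, since the deposited unit is FPKM. The recovered whole reads would have allowed a count model. The reported test is limma on log2(FPKM + 1). Cdh1 rose in each alternative (log2 fold change 1.47 to 1.82). For the other named genes and lists, 2975 values kept direction and side of the threshold, 33 gained a call, 130 lost one and 50 reversed.

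Without 1 library each, the changed genes ranged from 1251 to 5435, those higher from 471 to 2697 and those lower from 780 to 2738. Log2 fold changes ranged from -0.68 to -0.35 for Arhgap31, -0.60 to -0.41 for Zeb2, -0.011 to 0.066 for Cdc42, -0.065 to 0.012 for Zeb1, -1.02 to 0.42 for Rrm1, -1.77 to 0.16 for Rrm2, -0.44 to 0.48 for Mcm7, -0.86 to 0.17 for Mcm6, -1.38 to 0.39 for Top2a, -0.92 to 0.96 for Mki67, -1.33 to 0.28 for Anln and -1.32 to 0.30 for Cdk1. List medians ranged from -0.91 to 0.21 for DNA replication, -1.15 to 0.56 for mitosis, -0.060 to 0.056 for EMT factors, -0.17 to 0.11 for NRF2 targets, -0.15 to 0.24 for basal and -0.083 to -0.062 for endothelial markers. The upper ends of the proliferation genes and lists were reached without shCdGAP replicate 1.

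Without both libraries numbered 1, 6584 genes changed (3312 higher, 3272 lower), Arhgap31 passed at -0.38 (adjusted p = 0.00893, limma), and fold changes were 0.042 for Zeb1, 0.25 for Rrm1, 0.39 for Mcm7, 0.094 for Mcm6, 0.19 for Top2a, 0.78 for Mki67, 0.19 for Anln and 0.091 for Cdk1. List medians were then 0.073 for DNA replication, 0.39 for mitosis, -0.017 for EMT factors, -0.058 for basal and -0.089 for endothelial markers.

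With no filter, which tests more genes, Zeb2 kept its fold change of -0.53 and lost its call (adjusted p = 0.0589), and at a mean of 5 CPM, which tests fewer, 1960 genes changed, 1038 higher and 922 lower. Genes past an absolute log2 fold change of 1 numbered 1674 in limma-voom, 1576 with log2(FPKM + 0.1) and 2176 in the authors' deposited table, against 827; a pseudocount of 1 FPKM shrinks low genes. Directions also turned for Cdc42 (-0.028 with library size alone, -0.059 with quantile scaling), Zeb1 (0.0091 with TMM, 0.00305 with quantile scaling) and, in the authors' deposited table, Mcm7 (0.084) and Mki67 (0.32). List tests turned direction for NRF2 targets (median 0.061 with no filter, with the block and by ranks, 0.063 at 5 CPM, 0.062 with the block and GC, 0.050 with the block and length), EMT factors (-0.033 at 5 CPM and by fry), basal markers (-0.0065 with no filter) and endothelial markers (-0.040 with no filter, -0.51 with log2(FPKM + 0.1), -1.16 in limma-voom); the cause was not tested. Camera called 0 lists with an estimated correlation. Fry called 18, and of the 11 reported calls it left out sterol synthesis (adjusted p = 0.159) and ribosomal proteins (0.220). Among reported lists that camera did not call, fry called mesenchymal genes (adjusted p = 0.0031) and YAP and SRF targets (0.0305) as higher. It called as lower integrins and focal adhesion (0.00511), matrix proteases (0.00135), Notch (0.0031), and luminal (0.00135), fibroblast (0.0031) and leukocyte markers (0.0305).

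With the replicate number as a block, 2458 genes changed, 2183 of them shared with the 2838 in direction. Besides its effects on Snai2, Cidec and the DNA replication and immediate-early lists, given with those results, the block ended the calls on Slc3a2 (adjusted p = 0.0506) and Flt1 (0.0832) and changed no other call among the reported genes and lists. No scaling moved the median of all genes by more than 0.1 on the log2 scale (largest -0.052) nor the higher share, 47.1%, by more than 10 points (39.5% with library size alone, 53.4% with TMM). Depth limits genes near the floor of 3 reads, such as Twist1.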

Other observations

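The tests of gene families, of changed genes in other splits, of chromosome number, of admixed control cells, of sequencing depth and of a shared day were chosen after the results were seen. Of these, 2 were also changed once their outcome was known. The chromosome number test first covered chromosome 17 alone, where 100% of windows met its bound of 90%, and was widened to all shifted chromosomes with the bound kept. The admixture genes were first those close to silent in all 3 shCdGAP libraries, a choice that forced a low value (0.523%), and were picked again on replicates 2 and 3 alone. A test of whether genes close to silent had too few reads was dropped, because choosing them by level largely fixed its outcome. The remaining tests had predictions written before their own outcomes, but none was in the design fixed before the data were examined. That on GC content and gene length was set on chromosome 17, which had the largest shift.

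Across 300 families of genes that share a symbol stem and have at least 6 tested members, 2 were enriched among changed genes (Fisher's exact test, 1-sided in each direction, adjusted over 600 tests, against 12046 protein-coding genes). All 8 tested members of the Ugt family, UDP-glucuronosyltransferases that conjugate lipophilic compounds, rose, with a median log2 fold change of 0.88 (adjusted p = 7.22e-06). Ugt1a7c went from a mean of 1.23 to 13.3 FPKM and Ugt2b36 from 0.262 to 6.50, both named after their values were seen. Ugt1a genes share exons and Ugt2b genes are close in sequence, so these members are not independent and their reads are uncertain. Of 9 Ccl chemokine genes, 6 rose and 0 fell, with a median log2 fold change of 0.73 (adjusted p = 0.0221). Ccl20, also named after its values were seen, went from 1.61 to 34.3 FPKM.

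Among the 10 splits of the 6 libraries into 3 against 3, 1 gave as many changed genes as the real one, which was the real one itself, with 2838 against at most 0 in the others (limma). At an unadjusted p under 0.05 the other 9 splits held 15 to 647 genes, against 4661, and the 3 others that part all pairs of equal number held at most 258. Every other split mixes the groups on both sides, which puts their difference into the spread, so few changed genes were to be expected there. These gene counts therefore do not measure what chance would give. For gene lists, 2 of 10 splits gave as many calls by camera at the preset correlation, with 11 in the real split and 6 to 12 in the others. The highest set shCdGAP replicate 1 with shCON replicates 1 and 3. Camera at this setting called lists in every split, so the number of lists called does not set the real grouping apart. With 10 splits no share under 0.05 can be had.

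Genes of whole chromosomes shifted together: among 8883 protein-coding genes with a mean of at least 3 FPKM, 13 of 20 chromosomes had a median log2 fold change, relative to that of all these genes, beyond 10000 shuffles of genes over chromosomes (7 higher and 6 lower, adjusted p under 0.05, smallest p 1e-04, the smallest the shuffles can give). Chromosomes 17, 13, 19 and 8 lay highest, at 0.37, 0.28, 0.26 and 0.23, and chromosomes 16, 10 and 2 lowest, at -0.29, -0.21 and -0.21, whereas no shCON library moved a chromosome by more than 0.0527 from the other shCON libraries. The shCdGAP libraries differed more, with 0.19, 0.18 and 0.33 for chromosome 8 and 0.099, 0.0060 and 0.034 for chromosome 15 in replicates 1, 2 and 3. Chromosomes 7 and 15, counted among the 13, lay at 0.041 and 0.061, the former within that shCON range. The shuffles take genes as units, so their p-values do not measure the spread between libraries. Trends on GC content and gene length are argued against as the whole cause, since chromosome 17 stood at 0.352 with both removed and the 13 chromosomes kept 77.2% to 99.6% of their shift. A difference in chromosome number between the populations may contribute: 282 of 315 windows of 20 genes (89.5%) shifted the way of their chromosome, just under the bound of 90%, and it cannot be told apart from regulation because DNA was not measured. Depletion of CdGAP itself stays open as a cause, untested, as does divergence of the populations before or after the hairpin was introduced.

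Some genes were close to silent in one group and expressed in the other, under 0.5 FPKM in each library of one and at least 5 FPKM and 20 times higher in each of the other: 16 in shCdGAP and 10 in shCON, 20 of them protein-coding. Each other split of the libraries gave 0, which adds no support, because these splits mix the groups on both sides, where the rule can hardly be met. They held 0 to 123 reads in the silent group, where 125.9 to 9320 (median 1976.5) would stand at the level of the other group. Gatm, Klhl13, Micu2, Mgmt, Cd34 and Procr were close to silent in shCdGAP, and Loxl2, Fam20c, Ehf, Dio3, Alpl and Poglut1 in shCON, the last at 38525137 to 38550258 on chromosome 16, close to Arhgap31, with 25 reads in shCON and 1971 in shCdGAP (Klhl13, Micu2, Mgmt, Fam20c, Dio3 and Poglut1 were named after their values were seen). Loss of chromosome segments that reach the nearest expressed neighbours is argued against as a general cause for genes silent in shCdGAP. These 32 neighbours had a median log2 fold change of -0.311 (95% bootstrap interval -0.428 to -0.0463), although losses confined to single genes stay open. The interval lies below 0 and takes the neighbours as independent, though they come in pairs, whose means ran from -0.80 to 0.46. Their distance was not limited, and the shifts of whole chromosomes were not removed. Neighbours of genes silent in shCON were not tested. Lasting silencing in the cells from which each population grew is a candidate explanation, as is the depletion of CdGAP, and neither was tested.

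Replicate 1 of shCdGAP stood apart: 1265 genes lay over 1 log2 unit from the mean of replicates 2 and 3, 750 of them lower, against 49 genes for shCON replicate 1, and its mitosis and DNA replication medians lay at -3.39 and -2.14, against -0.50 and -0.41 for shCON replicate 1. Control cells mixed into it are argued against as the cause, since 27 genes that lay over 20 times below shCON in replicates 2 and 3 had a median of 1.54% of the shCON level in replicate 1 (quartiles 0.404% and 3.04%), and all 27 lay under 10%. Low depth is argued against too, as its reads came to 96.5% of the mean of the other 5 libraries. A day or batch shared by the libraries numbered 1 may contribute, because their deviations from the group means correlated at 0.432 across genes (slope 1.12, 18.7% of the variance of shCdGAP replicate 1), but the labels give no day, so this cannot be told apart from a difference in the growth of that culture. Whether the culture had stopped dividing was not measured apart from these transcripts. This library also held the least Arhgap31, at 0.149 FPKM against 0.826 and 0.748 in replicates 2 and 3. A stronger depletion therefore cannot be told apart from the causes above, and its part was not tested.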
